A study of Homo sapiens with 6 samples.

How the data were processed

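Polyadenylated RNA of LN229 cells was made into Illumina TruSeq libraries, 3 from untreated cells and 3 from cells treated with 800 µM UDCA for 48 h, per the labels' protocols. The submitters' processing notes name HISAT2, Bowtie2 2.0.6 and the build GRCh38, with no role or order. The counting program, its treatment of strand, of reads in several places and of overlapping genes, and the filters are not given in the sources used here. The deposited table gives 1 value per gene and library for 33890 genes. Its unit is not named there and was inferred from the values: the deposited values are FPKM, reads (or read pairs) scaled by the merged exon length of the gene and by the total of reads over the listed genes. The reasoning is that each value times the merged exon length of its gene in GENCODE 29 (Ensembl 94) is a whole multiple of 1 step per library. That held for 100% of values in each library within a tolerance of 0.01 reads, and the step equals the inverse of the summed whole numbers. The coordinates of all 33890 genes equal those of GENCODE 29, from which symbols and positions were taken. No gene was at 0 in every library. FPKM as deposited carries no scaling between libraries beyond the total, so a few abundant genes that rise or fall shift all others.

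The whole numbers recovered in this way were read as reads (or read pairs, which cannot be told from the table). They sum to 16639832, 17203507 and 17743022 in control replicates 1 to 3 and to 15988951, 17045218 and 16975081 in UDCA replicates 1 to 3. A count of 3 reads in a gene of 1 kb corresponds to 0.169 to 0.188 FPKM, which sets the precision of low values, for counting error only.

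Groups follow the labels. The design fixed before the data were examined put a count model first and, for a table of FPKM without counts, limma-trend on log2(FPKM + 1), so the latter was used. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested (14380), with the group as the only term, limma 3.58.1 in R 4.3.3, 2-sided, and Benjamini-Hochberg adjustment over all genes tested at 0.05. A log2 change on this scale understates the change of low genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Of 30 gene lists fixed before the data were examined, 28 had tested members. They were tested with camera (limma) at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Some genes belong to more than 1 list and count in each.

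Genes named in the text follow a rule fixed in advance: 20 genes chosen for the treatment and cell type, whatever their result; the 8 largest rises and 8 largest falls among called genes with a mean of at least 2 FPKM in the higher group, a symbol and groups that do not overlap; and up to 4 called members per list with the largest change and at least 2 FPKM. Genes named only by a clone, and pseudogenes, were passed over. Not every gene that the rule picks is described in the text. Members outside the rule are named where a count of 5 or fewer covers them or where the text says so; these were chosen after their values were seen.

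The test was checked on simulated reads for UDCA against control, drawn with the mean shares of the control libraries and the 6 totals, with 200 genes changed. At a dispersion of 0.00014, estimated from well-covered genes of the control libraries, 56 of 67 genes changed 1.5-fold, 65 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered, with 16 false calls among 13699 genes. At a dispersion of 0.01, set first as a round value, the numbers were 29 of 67, 63 of 67 and 64 of 66, with 14 false calls among 13693 genes. The false calls are out of all genes tested, not out of the calls. With 200 genes changed and 1 dispersion for all genes, the check does not cover data where most genes differ.

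Replicates were compared before they were averaged. Pairs of control libraries differed by a chi-square of 1.68 to 2.00 per degree of freedom over genes with at least 20 reads, and pairs of UDCA libraries by 1.69 to 2.95, with UDCA replicate 3 furthest from the others. These exceed sampling noise, and each library was counted as 1 sample. Such spread can be technical and does not show that the libraries came from separate cultures.

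Alternatives fixed in advance were quantile normalization, no filter on low values, a pseudocount of 0.1 in place of 1, the replicate number as a block, leaving out each library in turn, and the other list tests. Added after seeing the data were scaling by the median ratio of genes, totals without mitochondrial genes, and limma's voom on the recovered reads, which called 11747 genes. Overlap of exons between genes was taken from GENCODE 29 on either strand.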

Results

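Messenger RNA of LN229 cells, an established human glioblastoma line that grows attached in culture, was sequenced with and without ursodeoxycholic acid (UDCA), a secondary bile acid used as a drug in cholestatic liver disease. The labels give 2 groups of 3 libraries: untreated control cells, and cells kept in 800 µM UDCA for 48 h. The reads recovered from the deposited values came to 16639832, 17203507 and 17743022 in the control libraries and to 15988951, 17045218 and 16975081 in the UDCA libraries, so depth was similar in both groups. Values below are mean FPKM ± SD over 3 libraries (n = 3 in each group), folds are ratios of those means, and log2 changes are UDCA minus control on the log2(FPKM + 1) scale, which understates the change of genes near or under 1 FPKM. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

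The study's title places the work in a test of UDCA against glioblastoma, and the design holds 1 comparison, UDCA against control. Proliferation genes and mitochondrially encoded transcripts fell in the treated libraries, while stress-response genes of the ATF4 pathway and inflammatory cytokine genes rose. Of 14380 genes tested, 11624 (80.8%) differed at an adjusted p under 0.05, 6491 higher and 5133 lower with UDCA. Of them, 3492 differed at least 2-fold on the log2(FPKM + 1) scale, not by the ratio of means (1771 higher and 1721 lower). That count was 4688 with a pseudocount of 0.1 in place of 1. The groups did not overlap in 11907 tested genes (82.8%), where chance gives 10% for 3 against 3. The median gene rose by 0.095 on the log2 scale. Scaling the libraries by the median ratio of genes, an alternative added after seeing the data, moved that median to 0.003 and the calls to 5827 higher and 5786 lower. Profiles correlated at r = 0.989 or more within a group and at r = 0.768 or less between groups, across genes, which are not independent replicates. The first principal component of the log2 values held 94.4% of the variance. Of 28 gene lists with tested members, 18 passed the competitive list test at an adjusted p under 0.05, 8 of them higher and 10 lower, and 5 also passed with an estimated inter-gene correlation. Adjusted over the list alone, 25 of the 28 lists had the counts of higher and lower members given below; the other 3 are named with theirs.

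**Figure D1:**
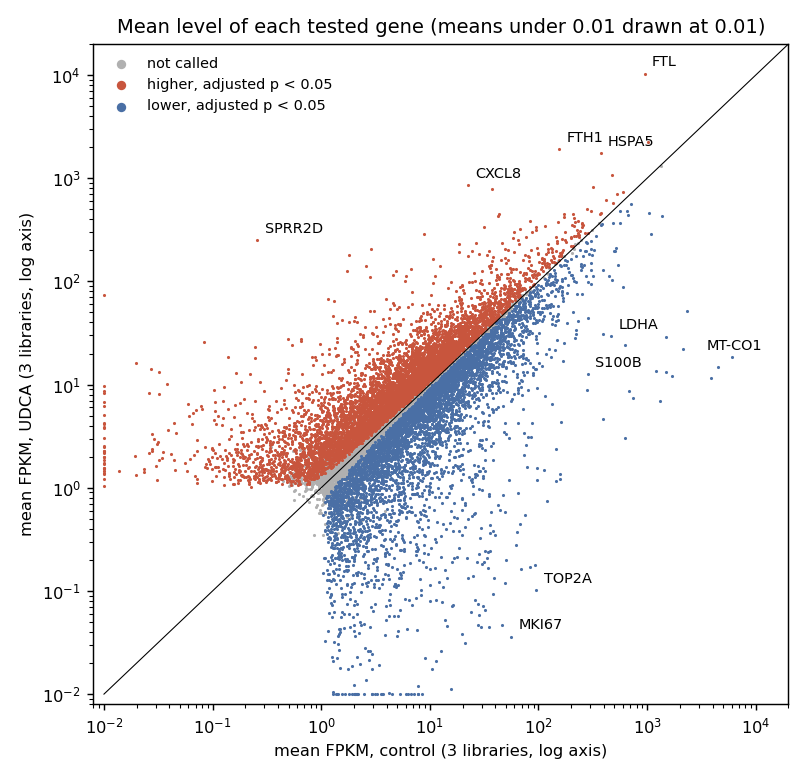
Mean FPKM of each tested gene in the 3 control libraries (x axis, log) against the 3 UDCA libraries (y axis, log), colored by call, with the line of equal means. MT-CO1 and the proliferation genes TOP2A and MKI67 lie far below the line, and SPRR2D, CXCL8, FTL and FTH1 far above it.

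The largest rises by the log2 change, among called genes with at least 2 FPKM in the higher group, were those of SPRR2D, CXCL3, PTX3, LCN2, ATF3, CXCL8, BEX2 and TRIB3. SPRR2D (chromosome 1, 153039725 to 153041931, GRCh38), a cornified-envelope gene of squamous epithelia, went from 0.258 ± 0.169 to 252 ± 42.3 FPKM, on 14 reads in all control libraries and 13303 in all UDCA libraries. Its near-identical SPRR2 paralogs make this value uncertain. PTX3, which encodes a secreted pattern-recognition protein, rose 71.6-fold from 2.90 ± 0.512 to 207 ± 5.53 FPKM. LCN2, the iron-siderophore binding lipocalin, rose 73.2-fold from 1.71 ± 0.164 to 125 ± 3.10 FPKM, and BEX2 rose 39.7-fold to 110 ± 3.83 FPKM. The 8 largest falls by the same rule were all mitochondrially encoded: MT-CO3, MT-CO1, MT-CO2, MT-ND5, MT-ND6, MT-CYB, MT-ATP6 and MT-ND4. By the ratio of means, MKI67 (1552-fold) and TOP2A (933-fold), both under 1 FPKM with UDCA, fell further than MT-CO3 (340-fold).

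Mitotic genes fell to near 0 in the treated cells for most members of their list. All 36 tested members of the G2/M list were lower, and the median member stood at 0.868% of its control level, with a median log2 change of -4.71 (adjusted p = 2.24e-18, and adjusted p = 0.00842 with an estimated correlation). MKI67 (chromosome 10, 128096659 to 128126385), the gene of the proliferation marker Ki-67, went from 56.1 ± 0.977 to 0.0362 ± 0.0129 FPKM, on 37087 reads in all control libraries and 23 in all UDCA libraries. TOP2A, the DNA topoisomerase of dividing cells, fell from 95.7 ± 2.59 to 0.103 ± 0.01004 FPKM, and the survivin gene BIRC5 fell from 93.4 ± 2.02 to 0.178 ± 0.0335 FPKM. CCNB1, the mitotic cyclin B1, fell 61.6-fold from 96.1 ± 1.63 to 1.56 ± 0.170 FPKM. KIF20A, a kinesin of cytokinesis, fell from 84.1 ± 0.733 to 0.171 ± 0.0489 FPKM, on 17170 and 34 reads, and CDC20, an activator of the anaphase-promoting complex, fell 161-fold.

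DNA replication genes fell with them. In the G1/S list 38 of 39 tested members were lower and none was higher, with a median log2 change of -2.83 (adjusted p = 9.01e-16, and adjusted p = 0.00842 with an estimated correlation). The member that did not pass was CCNE1, at 3.94 ± 0.325 and 3.44 ± 0.0947 FPKM, which was called when adjusted over the list alone (39 lower). PCNA, the sliding clamp of the replication fork, fell 7.77-fold from 217 ± 3.36 to 28.0 ± 0.568 FPKM. TK1, thymidine kinase 1, fell 129-fold from 158 ± 4.27 to 1.22 ± 0.0609 FPKM, and the transcription factor E2F1 fell 42.2-fold from 34.9 ± 1.13 to 0.826 ± 0.210 FPKM. RRM2, a ribonucleotide reductase subunit, fell 165-fold, and CDC45, part of the replicative helicase, fell from 24.1 ± 1.11 to 0.0629 ± 0.0352 FPKM, on 3548 reads in all control libraries and 9 in all UDCA libraries. Among D-type cyclins, their kinases and the CDK inhibitors, 8 of 11 tested members were lower and 2 higher (median log2 change -0.89, adjusted p = 0.0162, and adjusted p = 0.124 with an estimated correlation). The 2 higher were CDKN1A and RBL2, a retinoblastoma relative. CCND1, cyclin D1, moved little by comparison, from 102 ± 2.34 to 83.2 ± 1.16 FPKM (adjusted p = 2.2e-05). CDKN1A, which encodes the inhibitor p21, rose 1.41-fold from 54.6 ± 1.17 to 77.1 ± 3.87 FPKM (adjusted p = 2.1e-05). RBL1, of the same family as RBL2, fell 6.27-fold, CDK2 fell 4.98-fold and CCND3 fell 2.96-fold.

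Transcripts made from the mitochondrial genome nearly dropped out of the treated libraries. All 13 protein genes of that genome were lower, with a median log2 change of -6.70 (adjusted p = 6e-09, and adjusted p = 0.0161 with an estimated correlation). Mitochondrially encoded genes took 3.15% ± 0.0156 of all recovered reads in control and 0.0267% ± 0.000399 with UDCA. MT-CO1 (positions 5904 to 7445 of the mitochondrial chromosome), the catalytic subunit of cytochrome oxidase, fell 328-fold from 6058 ± 76.0 to 18.5 ± 0.900 FPKM. MT-CO3 fell 340-fold from 3912 ± 58.6 to 11.5 ± 1.59 FPKM, and MT-CO2 fell 304-fold from 4489 ± 29.95 to 14.7 ± 0.533 FPKM. Genes of complex I fell by unequal factors: MT-ND5 fell 188-fold, MT-ND6, the member on the light strand, fell 208-fold, and MT-ND4 fell 95.7-fold. MT-CYB fell 141-fold and MT-ATP6 fell 111-fold. MT-ATP8 overlaps MT-ATP6 and is weakly covered: it was listed at 19.2, 2.25 and 1.91 FPKM in the control libraries and at 0 in each UDCA library, at least 26.2-fold lower against a floor of 3 reads over the group. Of its 81 control reads 66 came from control replicate 1, without which the bound was 7.16-fold. With that gene at its bound, the list's median stayed at -6.70. Reads of mitochondrial genes are shared with nuclear copies, so single values are uncertain where counting split them.

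**Figure D2:**
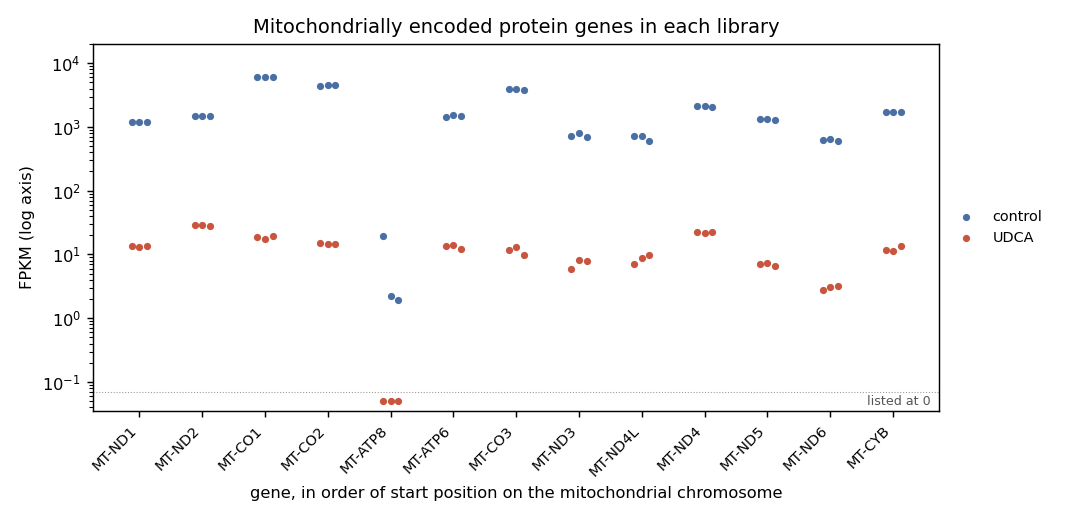
FPKM (log axis) of the 13 mitochondrially encoded protein genes in each of the 3 control and 3 UDCA libraries, in order of start position on the mitochondrial chromosome, each point 1 library. Every control point lies above every UDCA point of the same gene, and the UDCA points of MT-ATP8 are listed at 0.

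Nuclear genes of the same respiratory complexes moved far less. Of 34 tested nuclear oxidative phosphorylation genes, 20 were lower, 7 higher and 7 did not pass, with a median log2 change of -0.20 (adjusted p = 0.0309, and adjusted p = 0.31 with an estimated correlation). With median-ratio scaling 23 were lower and 4 higher and the median was -0.31, and with voom on recovered reads it was -0.32. ATP5F1B, the beta subunit of ATP synthase, fell 1.99-fold from 302 ± 2.19 to 152 ± 2.89 FPKM, COX8A fell 1.78-fold and SDHC fell 1.62-fold, while NDUFA10 rose 2.29-fold.

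Genes of the ATF4 integrated stress response rose together. Of 29 tested members, 27 were higher and 1 lower, with a median log2 change of 2.003 (adjusted p = 9.86e-09, and adjusted p = 0.0161 with an estimated correlation). DDIT3 (chromosome 12, 57516588 to 57521737), which encodes the stress-induced transcription factor CHOP, rose 19.7-fold from 6.64 ± 0.584 to 131 ± 2.90 FPKM. Of its exon bases 39.6% lie within exons of other annotated genes, so its level is uncertain. ATF3 rose 55.1-fold from 2.57 ± 0.159 to 142 ± 2.83 FPKM, TRIB3 rose 32.0-fold to 285 ± 7.43 FPKM, and STC2, a secreted glycoprotein, rose 25.5-fold to 116 ± 1.80 FPKM. ATF4 itself rose 2.64-fold from 170 ± 3.28 to 450 ± 16.3 FPKM. ASNS, asparagine synthetase, rose 17.5-fold from 0.566 ± 0.00420 to 9.92 ± 0.879 FPKM, with 44.6% of its exon bases inside another gene. The member that was lower was VLDLR, from 5.38 ± 0.552 to 2.58 ± 0.0393 FPKM, and SLC7A5 did not pass at 247 ± 2.06 and 251 ± 5.98 FPKM. The aminoacyl-tRNA synthetases, enzymes that charge tRNAs with amino acids, had 15 of 18 members higher and 2 lower, with a median log2 change of 1.33 (adjusted p = 0.000122, and adjusted p = 0.0514 with an estimated correlation). AARS rose 5.07-fold from 59.7 ± 0.528 to 303 ± 4.16 FPKM, and YARS rose 4.64-fold, while DARS and QARS were the 2 lower.

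The chaperones and degradation factors of the endoplasmic reticulum split. Of 29 tested members, 17 were higher and 11 lower, and the list did not pass (adjusted p = 0.207). HSPA5 (chromosome 9, 125234853 to 125241330), the chaperone BiP, rose 4.67-fold from 373 ± 2.50 to 1741 ± 37.9 FPKM, and the transcription factor XBP1 rose 8.80-fold from 26.6 ± 0.969 to 234 ± 5.05 FPKM. DNAJB9 rose 12.5-fold and HERPUD1 rose 8.98-fold. In the other direction, CALR, the chaperone calreticulin, fell 2.55-fold from 506 ± 1.83 to 198 ± 2.17 FPKM, and the disulfide isomerase PDIA6 fell 1.73-fold; both were chosen after their values were seen.

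Antioxidant genes of the NRF2 list were mostly higher: 22 of 29 rose and 6 fell, with a median log2 change of 0.93 (adjusted p = 0.000797, and adjusted p = 0.0577 with an estimated correlation). HMOX1, heme oxygenase 1, rose 26.2-fold from 4.85 ± 0.218 to 127 ± 1.62 FPKM, SOD2, the mitochondrial superoxide dismutase, rose 36.6-fold to 46.6 ± 2.27 FPKM, and OSGIN1 rose 17.2-fold. FTH1, the ferritin heavy chain, rose 12.3-fold from 155 ± 9.11 to 1912 ± 69.5 FPKM; ferritin genes have processed pseudogenes that share their reads, and 62.4% of the exon bases of FTH1 lie in exons of the opposite strand. Heat shock genes were higher in 17 of 22 and lower in 3, with a median log2 change of 0.70 (adjusted p = 0.000978, and adjusted p = 0.124 with an estimated correlation). HSPA1A rose 4.84-fold from 10.0 ± 0.344 to 48.4 ± 2.45 FPKM and HSPA1B rose 4.70-fold, though these are near-identical copies. HSPA4L rose 5.47-fold, and the 3 lower were HSPE1, HSP90AB1 and CRYAB. Among autophagy and lysosome genes 19 of 26 were higher and 6 lower, with a median log2 change of 0.45 (adjusted p = 0.013, and adjusted p = 0.149 with an estimated correlation). SQSTM1, which encodes the autophagy receptor p62, rose 10.3-fold from 42.3 ± 1.16 to 434 ± 12.6 FPKM, and MAP1LC3B, an LC3 gene, rose 3.43-fold.

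Inflammatory genes rose without exception among those tested. All 22 tested members of the NF-kappaB and cytokine list were higher, with a median log2 change of 3.02, or 3.11 with CSF2 and TNF, which had no reads in control, at their bounds (adjusted p = 1.5e-08, and adjusted p = 0.0161 with an estimated correlation). CXCL8 (chromosome 4, 73740506 to 73743716), the neutrophil chemokine interleukin 8, rose 37.9-fold from 22.6 ± 1.04 to 856 ± 55.0 FPKM. CXCL3 rose 99.3-fold from 1.81 ± 0.383 to 180 ± 4.24 FPKM, IL1A, interleukin 1 alpha, rose 49.8-fold to 64.7 ± 0.564 FPKM, and the receptor-associated kinase IRAK2 rose 27.3-fold to 42.0 ± 1.25 FPKM. The interferon list went both ways, with 18 of 24 higher and 6 lower, and did not pass (adjusted p = 0.0725). IRF1 rose 16.9-fold from 1.35 ± 0.0949 to 22.8 ± 0.844 FPKM and IFIH1 rose 6.35-fold, while IFIT2 fell 8.41-fold from 10.4 ± 0.343 to 1.23 ± 0.0352 FPKM and OAS3 fell 6.70-fold.

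**Figure D3:**
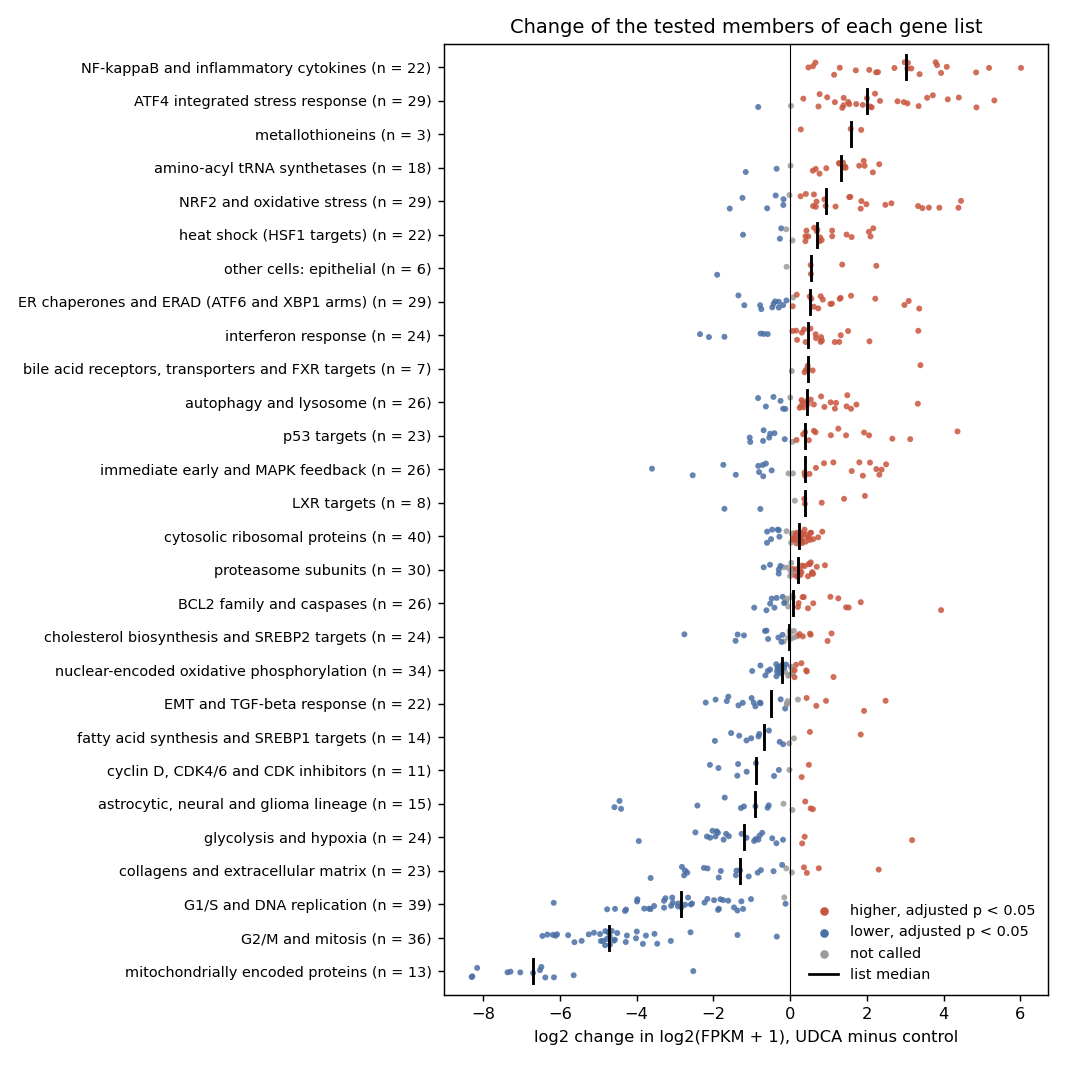
Log2 change (x axis, UDCA minus control on the log2(FPKM + 1) scale) of the tested members of each gene list, each point 1 gene, with the list median as a bar and the number of tested members in brackets. The medians run from -6.70 for mitochondrially encoded proteins to 3.02 for NF-kappaB and inflammatory cytokines.

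The list of glycolysis and hypoxia genes had 21 of 24 tested members lower and 3 higher, with a median log2 change of -1.20 (adjusted p = 8.3e-07, and adjusted p = 0.0824 with an estimated correlation). LDHA, lactate dehydrogenase A, fell 15.9-fold from 465 ± 3.00 to 29.3 ± 0.653 FPKM, PGAM1 fell 5.64-fold and TPI1 fell 4.52-fold from 472 ± 7.19 to 104 ± 2.89 FPKM. VEGFA, the angiogenic growth factor in this list for its response to hypoxia, rose 10.6-fold from 5.02 ± 0.254 to 53.5 ± 0.915 FPKM; the other members higher were PFKP and PFKM. Fatty acid synthesis genes were lower in 10 of 14 and higher in 2, with a median log2 change of -0.68 (adjusted p = 0.0118, and adjusted p = 0.207 with an estimated correlation). FASN, fatty acid synthase, fell 2.94-fold from 136 ± 2.09 to 46.3 ± 1.25 FPKM, FADS2 fell 5.94-fold and SREBF1 fell 2.72-fold, while the malic enzyme gene ME1 rose 3.82-fold and the desaturase gene FADS1 was the other member higher.

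Cholesterol synthesis genes went both ways, with 7 of 24 higher and 10 lower, and the list did not pass against other genes (camera, adjusted p = 0.228). Fry, which makes no such comparison, called the list lower (adjusted p = 1.1e-05). EBP, a sterol isomerase of the pathway, fell 2.86-fold from 16.1 ± 0.422 to 5.64 ± 0.475 FPKM, and ACAT2 fell 3.22-fold from 4.58 ± 0.230 to 1.42 ± 0.0379 FPKM, with 52.3% of its exon bases inside exons of other genes. Among LXR targets 5 of 8 were higher and 2 lower (adjusted p = 0.391): ABCA1, the cholesterol efflux pump, rose 5.82-fold from 1.46 ± 0.0411 to 8.51 ± 0.114 FPKM and PLTP rose 2.83-fold, while MYLIP fell 4.03-fold. The others higher were NR1H2, NR1H3 and SMPDL3A, and LPCAT3 was the other lower. Of the bile acid receptors, transporters and targets only 7 reached the minimum level, of which 6 were higher and none lower (median log2 change 0.46, adjusted p = 0.0453, and adjusted p = 0.168 with an estimated correlation). That list call was lost without control replicate 3 (adjusted p = 0.05105), UDCA replicate 1 (0.0516) or UDCA replicate 3 (0.06097), and also with median-ratio scaling (0.05345), voom on recovered reads (0.05158), a replicate block (0.05112) or no filter on low values (0.554), over a range of 0.0397 to 0.554. ABCC3, a bile salt exporter, rose 14.3-fold from 2.51 ± 0.161 to 35.95 ± 1.04 FPKM. NR3C1, the glucocorticoid receptor, rose 1.55-fold from 10.1 ± 0.388 to 15.7 ± 0.540 FPKM, and the vitamin D receptor VDR rose 1.38-fold. GPBAR1, the membrane bile acid receptor TGR5, was under the minimum at 0.224 ± 0.105 and 0.111 ± 0.0571 FPKM and was not tested. NR1H4, which encodes the nuclear receptor FXR, was not among the genes listed and so was not tested.

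Extracellular matrix genes were lower in 17 of 23 and higher in 4, with a median log2 change of -1.30 (adjusted p = 5.42e-05, and adjusted p = 0.0944 with an estimated correlation). VCAN, the proteoglycan versican, fell 15.1-fold from 64.6 ± 1.31 to 4.28 ± 0.0306 FPKM, SPARC fell 6.85-fold from 600 ± 5.18 to 87.5 ± 2.59 FPKM, and THBS2 and the lysyl oxidase gene LOXL2 fell 7.25-fold and 7.32-fold. The 4 higher were COL5A1, COL6A1, COL6A2 and TIMP1. COL6A2, a collagen VI chain chosen after its value was seen, rose 5.04-fold from 46.6 ± 0.579 to 235 ± 8.46 FPKM. In the mesenchymal transition and TGF-beta list 13 of 22 were lower and 5 higher, or 13 and 6 adjusted over the list alone (median log2 change -0.51, adjusted p = 0.0287, and adjusted p = 0.124 with an estimated correlation). TGFB2 fell 17.3-fold and SNAI1, a repressor of E-cadherin, fell 4.07-fold, while CYR61 rose 5.92-fold. Others higher were SMAD7, ITGA5 and ACTA2.

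Glial and neural lineage genes were lower in 10 of 15 tested members and higher in 3, with a median log2 change of -0.90 (adjusted p = 0.0039, and adjusted p = 0.0944 with an estimated correlation). That median was -1.42 with a pseudocount of 0.1 and -1.55 with voom on recovered reads. S100B, a calcium-binding protein of glia, fell 22.8-fold from 286 ± 10.1 to 12.5 ± 0.0593 FPKM, and SOX2, a stem cell transcription factor, fell 29.9-fold from 77.0 ± 1.49 to 2.58 ± 0.0887 FPKM. FABP7, the brain fatty acid binding protein, fell from 27.4 ± 0.771 to 0.191 ± 0.0544 FPKM, on 3862 and 26 reads. NES, the intermediate filament nestin, fell 5.50-fold from 148 ± 4.39 to 26.9 ± 0.280 FPKM. The 3 higher were EGFR, the receptor of epidermal growth factor, PDGFRB and HEY1.

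Genes of cell death went both ways and did not stand out from other genes as a list. In the BCL2 and caspase list 12 of 26 were higher and 8 lower (camera, adjusted p = 0.616). The median log2 change of 0.07 turned to -0.04 with median-ratio scaling and with voom on recovered reads. Fry, which makes no comparison with other genes, called the list higher (adjusted p = 5.54e-05), as it called all 28 lists. MCL1, a survival factor, fell 1.54-fold from 164 ± 0.664 to 107 ± 2.07 FPKM. BCL2 was at 1.44 ± 0.110 and 1.13 ± 0.0684 FPKM (adjusted p = 0.0377). That call was lost without control replicate 1 (adjusted p = 0.0853) or 3 (0.103), and without UDCA replicate 1 (0.0843), 2 (0.0517) or 3 (0.101). It was also lost with a replicate block (0.0885) or no filter on low values (0.107). Over all alternatives the adjusted p ranged from 7.6e-05 to 0.107. BIRC3, an inhibitor of apoptosis and an NF-kappaB target, rose 74.1-fold from 0.243 ± 0.0388 to 18.0 ± 1.38 FPKM, the inflammatory caspase gene CASP4 rose 5.83-fold and PMAIP1, which encodes NOXA, rose 2.84-fold. Of p53 targets 14 of 23 were higher and 8 lower (adjusted p = 0.18). GDF15 rose 21.1-fold from 37.6 ± 1.18 to 792 ± 27.1 FPKM, GADD45A rose 6.52-fold and the death receptor gene TNFRSF10B rose 4.25-fold.

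Ribosomal protein genes were higher in 30 of 40 and lower in 7, with a median log2 change of 0.24 (adjusted p = 0.0162, and adjusted p = 0.551 with an estimated correlation). With median-ratio scaling the counts were 22 higher and 9 lower, the median was 0.13 and the list did not pass (adjusted p = 0.104); it did not pass with voom on recovered reads either (0.0773), and over the alternatives its adjusted p ranged from 0.000237 to 0.551. RPS27 rose 1.79-fold and RPS2 fell 1.52-fold. Proteasome genes were higher in 19 of 30 and lower in 5 (adjusted p = 0.107), or 15 and 10 with median-ratio scaling. PSMD7 rose 1.64-fold and PSMC3 fell 1.63-fold. Without that scaling the others lower were PSMB3, PSMB4, PSMB5 and PSMD2. The 3 tested metallothioneins, MT1E, MT1X and MT2A, were higher (adjusted p = 0.0786), by 3.90, 7.92 and 1.21 times. Immediate early genes were higher in 14 of 26 and lower in 10, or 15 and 10 adjusted over the list alone (adjusted p = 0.567): MYC rose 6.57-fold and JUNB rose 5.34-fold, while EGR3 fell 20.3-fold and PHLDA1 fell 6.23-fold.

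Haematopoietic and endothelial markers were low in both groups, while some epithelial markers were not. No listed haematopoietic or endothelial marker reached the minimum for testing, with highest means of 0.341 ± 0.118 FPKM for CD14 and 0.851 ± 0.179 FPKM for ESAM, both in control. Of 6 tested epithelial genes, 4 were higher and 1 lower (adjusted p = 0.391). ESRP1, an epithelial splicing factor, rose 12.7-fold to 5.99 ± 0.278 FPKM, KRT8 rose 1.57-fold, CLDN4 and ELF3 were the others higher, and KRT14 fell from 2.84 ± 0.190 to 0.0263 ± 0.000952 FPKM, on 334 and 3 reads. KRT18 had the highest mean of the list, at 16.04 ± 0.656 and 15.0 ± 0.879 FPKM, and did not pass.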

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

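The median-ratio scaling, the totals without mitochondrial genes and voom were chosen after seeing the data. The count of 11624 genes stayed within 1.5 times under each alternative. It ran from 11218 to 11381 with 1 library left out and to 14451 of 33890 genes with no filter. The 3492 genes at least 2-fold apart on the log2 scale stayed within 1.5 times too. That count rose to 4688 with a pseudocount of 0.1 and 4791 with voom. Of 128 named genes tested, 127 kept direction and call under every alternative, and BCL2 kept its direction with adjusted p from 7.6e-05 to 0.107. Apart from those chosen whatever their result, the named genes were picked as called genes with large changes. Their stability therefore does not speak for the other calls. Of all 11624 calls, 10959 kept direction and call with voom, the fewest of any alternative. All 28 lists kept the direction of their test, while the median log2 change of the BCL2 and caspase list turned from 0.07 to -0.04 with median-ratio scaling and with voom. Of the 18 lists called, 5 passed with an estimated correlation, while fry, which asks another question, called 28. The estimated correlation was below the preset 0.01 for some lists that lost the call, such as NRF2 (-0.0187) and the tRNA synthetases (-0.0217). It was above 0.01 for others, such as the ribosomal list (0.45). For the former, a larger correlation does not account for the lost call. The bile acid list ranged from an adjusted p of 0.0397 to 0.554 with camera, and the ribosomal list lost its call with median-ratio scaling and voom. Lists gained were those of proteasome, interferon and metallothionein genes with quantile normalization, and of proteasome, metallothionein, p53 and endoplasmic reticulum genes with no filter. The cause of these list changes was not tested. The replicate numbers do not pair libraries by the data: deviations of same-numbered libraries from their group means correlated at 0.0143, -0.00119 and 0.00725, and no library correlated best with the 1 of its own number. With the replicate block 11503 genes were called, 3492 of them at least 2-fold on the log2 scale, and 17 lists. A count model on deposited counts and its alternatives were not run, since the table holds FPKM. Depth limits genes near 0.2 FPKM, where 3 reads in 1 kb stand.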

Other observations

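The genes in the first paragraphs here, the test of a common removal of mitochondrial reads and the tests of shared exons at a limit of 20% were chosen after their values were seen. Ferritin became one of the most abundant messages of the treated cells: FTL, the light chain, took 0.0831% ± 0.00049 of reads in control and 0.907% ± 0.00993 with UDCA, and rose from 946 ± 5.58 to 10335 ± 113 FPKM (adjusted p = 1.55e-10), with reads that its pseudogenes share. TXNRD1, thioredoxin reductase 1, rose 10.3-fold from 43.4 ± 1.20 to 446 ± 4.81 FPKM, while NQO1, a usual NRF2 target, was lower at 141 ± 2.76 against 160 ± 0.959 FPKM. SOX10, a transcription factor of the glial and neural crest lineage, fell 12.7-fold from 390 ± 3.28 to 30.8 ± 1.07 FPKM. TGFA, a ligand of the EGF receptor, fell 31.8-fold from 281 ± 1.38 to 8.82 ± 0.265 FPKM. IGFBP5 and IGFBP3, which encode binding proteins of insulin-like growth factors, went opposite ways: IGFBP5 fell 82.8-fold from 97.5 ± 2.91 to 1.18 ± 0.0843 FPKM and IGFBP3 rose 8.78-fold from 6.92 ± 0.351 to 60.7 ± 2.64 FPKM. HLA-DRA, an MHC class II gene, was at 489 ± 5.28 and 370 ± 8.71 FPKM, and CD74, which encodes the invariant chain, was at 482 ± 6.01 and 571 ± 19.8 FPKM. BEX4 rose with its neighbor on the X chromosome BEX2, 22.6-fold to 40.7 ± 2.37 FPKM. AC034213.1, a long noncoding RNA named only by its clone, had 0 reads in the control libraries and 2950 in the UDCA libraries, at 73.1 FPKM.

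Nuclear genes that copy or transcribe the mitochondrial genome, or act on its RNA, did not follow its transcripts. Of 15 tested, 6 were higher, 6 lower and 3 did not pass, with log2 changes from -1.002 for the termination factor MTERF1 to 0.82 for POLG2. POLRMT, the mitochondrial RNA polymerase, rose from 13.1 ± 0.185 to 21.5 ± 0.612 FPKM, TWNK, the helicase, rose from 11.8 ± 0.204 to 19.0 ± 0.0368 FPKM, and the packaging factor TFAM fell from 12.2 ± 0.575 to 8.33 ± 0.374 FPKM. The mitochondrial ribosomal RNAs fell less than most of the protein genes: MT-RNR1 fell 26.0-fold to 23.9 ± 0.449 FPKM and MT-RNR2 fell 45.2-fold to 51.4 ± 1.72 FPKM. MTATP6P1 and MTND2P28, pseudogenes on chromosome 1 that are near-copies of mitochondrial genes, fell 116-fold and 76.3-fold.

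Most tested genes differed, with 11624 of 14380 called, 3492 of them at least 2-fold on the log2 scale. Beside an effect of the treatment, which remains a hypothesis, 2 technical explanations were tested. A treated group from another cell line, or a mixed-up sample, would shift whole chromosome segments with their copy number. None of 148 windows of 20 Mb with at least 30 tested genes (0%) had a median log2 change more than 0.5 from that of all genes. The furthest was at 0.496, just under that limit. These values argue against a line or sample with large copy-number differences. The test was not tried on lines known to differ, so a line with smaller differences stays open. Degraded RNA or a length bias would part short from long genes, and the median log2 change of the 2876 longest genes differed from that of the 2876 shortest by -0.101, under the limit of 0.2 set beforehand. The 3 against 3 libraries allow 10 splits, of which 1, the real one, gave as many genes and the highest other gave 0; that is too few splits for a share under 0.05.

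The loss of mitochondrially encoded transcripts from these libraries is a result to follow up. The libraries were made from polyadenylated RNA, so the values do not tell a fall in RNA level from a fall in its capture. Removing 1 common share of mitochondrial reads from the treated libraries, and nothing else, would lower each gene alike. The log2 change of read share spanned 2.72 over the 12 protein genes with reads in both groups, from 51.6-fold to 340-fold lower. A common removal on top of changes of single genes stays open, since the largest counting error, 0.163, does not cover such changes. Removal of 1 common share alone did not explain the loss. Nor did abundant nuclear genes that take up reads explain it, since the median stayed at -6.80 after median-ratio scaling. A loss of whole mitochondria along with the nuclear messages for their respiratory chain would need a large fall of the latter, whose median changed by -0.20, or by -0.31 with median-ratio scaling and -0.32 with voom. A removal that leaves an unequal remainder stays open, as do faster decay or lower synthesis of mitochondrial RNA. Loss of mitochondrial DNA, and loss of mitochondria that leaves those nuclear messages in place, stay open too. None of these was tested. The fall of the nuclear copies cannot tell them apart, since mitochondrial genes share reads with those copies.

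Some genes that every cell uses are listed near 0 in all libraries, such as ALDOA, aldolase A, at 1.01 FPKM and NDUFS7 at 0.268 FPKM in control. A candidate explanation is that the authors' counting left out or split reads in exons that another annotated gene shares. The test set beforehand, on core genes with 80% or more of their exon bases shared, could not be made, since 0 genes of the 5 lists used reach that limit. At a limit of 20%, 17 such genes had a median of 2.94 FPKM in control, 6.28% of the 46.8 FPKM of 135 genes with less overlap, but 2 of the 17, CA9 and ANKRD37, are induced by hypoxia and not used by every cell. Without the 7 hypoxia genes of these lists the median of 15 genes was 6.72 FPKM, 13.6% of the 49.5 FPKM of 130 others, which misses the limit of 10% set for the test, with 7 of the 15 against 4 of the 130 under 5 FPKM (Fisher's exact test, 2-sided p = 7.46e-06), and 6 genes that overlap the opposite strand only had a median of 12.1 FPKM with 1 under 5 FPKM, so the explanation stays open.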
